A study of Mus musculus with 36 samples.

How the data were processed

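RNA was measured by sequencing in 36 libraries of peripheral blood, labelled erythrocytes, from Townes sickle cell mice, which carry human globin genes in place of the mouse ones. Per the labels, the mice received a scrambled control or MIR29B at 2 or 3 mg/kg from a mini-osmotic pump, blood was taken at weeks 0, 2 and 4, RNA was extracted with TRIzol, and globin mRNA was removed with the GLOBINclear kit. Per the labels, the submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and the genome build GRCm38, without saying what each was used for. The deposited table holds raw counts, not normalised, for 25856 RefSeq transcripts in the 36 libraries. Every count was even (0 odd values), and isoforms of one gene held nearly the same counts. The 9 transcripts of Prxl2a were an example, where the lowest total was 94.9% of the highest. How reads shared by isoforms were assigned is not stated. The labels do not give the annotation release, the strand setting or the handling of read mates.

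Transcript accessions were matched to gene symbols with a RefSeq table, 25645 of them, or with GENCODE, 137 of them. The remaining 74 had no symbol and held 1.04% to 10.07% of a library's counts. They were kept as entries of their own in the counts and the scaling, and none of them is named below. Each gene was represented by its transcript with the highest total count, which gave 16812 genes, the entries without a symbol included. Totals over all transcripts ranged from 10.7 to 45.65 M counts per library, with a median of 29.1 M. Over 1 transcript per gene they ranged from 6.82 to 31.72 M. Ribosomal RNA took 1.39% to 15.05% of the counts, with a median of 2.24%. The lowest library had 7411 genes with at least 10 counts, and the highest had 11220. Floors given for genes without counts use 3 counts over the summed libraries of a group, and cover counting error alone. Since every count was even, each fragment may have been counted as 2, and the fold by a floor of 6 counts is given beside it. Where a gene had only a few counts on 1 side, no floor is given, and its fold from the model rests on those counts.

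Genes were kept with edgeR's filterByExpr by group at a minimum count of 10 and a minimum total of 15, which left 11953 genes. Counts were scaled with the TMM method, and levels are given as TMM-scaled CPM. A quasi-likelihood model with 12 groups of 3 libraries, for week, dose and arm, was fitted to all 36 libraries with edgeR 4.0.16 in R 4.3.3. Each comparison was tested with the two-sided quasi-likelihood F test, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within the comparison. The common dispersion was 0.25, a coefficient of variation of 0.5 between libraries of a group. The comparisons were MIR29B against scrambled at each week and dose, week 2 and week 4 against week 0 within each arm averaged over the doses, the difference between arms in those changes, and the difference between doses in the MIR29B effect. Log2 fold changes are given with a standard error derived from the test. It is the absolute log2 fold change divided by the square root of its F statistic.

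Gene lists were fixed before the data were examined: miR-29 targets from the literature, DNA methylation machinery, fetal globin regulators, mouse globin genes, erythroid genes, and markers of neutrophils, monocytes and macrophages, B cells, T cells, NK cells, platelets and megakaryocytes, and eosinophils and basophils. The other lists held interferon-stimulated, inflammatory response, oxidative stress and NRF2, cell cycle, and heat shock and unfolded protein genes, ribosomal protein genes, and genes with the miR-29 8-mer site TGGTGCTA in the 3' UTR. Ribosomal protein genes were listed by a pattern of their symbols alone. The site was searched in 15185 genes with an annotated 3' UTR and found in 431. A list of mitochondrially encoded genes could not be tested, since too few of its members were in the table. Lists with at least 5 tested members were tested with camera from limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. Adjustment was over all lists and the comparisons of one kind together. The camera tests of weeks against week 0 and of the differences between arms and between doses were added after the data were examined.

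The genes named were set by a rule before the data were examined. For each comparison they are the 6 highest and 6 lowest fold changes among called genes with an established symbol, and up to 3 called members of each list. In every comparison of the arms 13 genes are named whether called or not: Dnmt3a, Dnmt3b, Dnmt1, Tet1, Tet2, Tet3, Bcl11a, Myb, Klf1, Gata1, Zbtb7a, Mcl1 and Col1a1. Of these, Col1a1 had too few counts to be tested. Where no gene was called, the 3 smallest p-values are named. Gene coordinates are those of the GENCODE annotation on GRCm38.

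The code was tested on simulated data with the design and dispersion of the study. Of 200 genes changed 2-fold, 1 was recovered in a comparison of 3 with 3 libraries, and 20 in a comparison of 6 with 6. Of 200 genes changed 4-fold, 97 and 175 were recovered, with 5 and 13 false calls. Genes were simulated independently of each other, without shifts shared by many genes of a library, so these false calls do not cover errors from such shifts. The alternatives tried were size factors by DESeq2's method, no filter on low counts, DESeq2 1.42.0, limma voom with sample weights and the compared libraries alone. The replicate number was also used as a block, within arm and dose for comparisons over weeks, and each library was left out. Alternatives chosen after the data were examined were isoforms summed, every transcript tested, counts halved, a term for sex read from the counts of a Y-linked gene, a term for transcript length, removal of libraries with over 5% ribosomal RNA or an extreme TMM factor, and other forms of voom weights. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.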

Results

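Gene expression was measured in peripheral blood of Townes sickle cell mice, a humanised model of sickle cell disease, to follow dosing with MIR29B and its effect on transcripts across the genome. MIR29B is a cholesterol-modified microRNA; microRNAs of the miR-29 family are known to target transcripts of DNA methyltransferases, and the series title names DNMT3A as the target through which fetal hemoglobin is induced. The 36 libraries fell into 12 groups of 3: scrambled control or MIR29B, at 2 or 3 mg/kg, at week 0, 2 or 4. Whether week 0 blood was taken before dosing began was not established. For week 0, wording such as with MIR29B therefore names the arm and not an exposure. Library totals were 10.7 to 45.65 M counts. The cell type is given as erythrocytes, and transcripts known from several blood cell types were counted. Alas2, the first enzyme of heme synthesis in red cells, took 5.32% to 13.62% of the counts assigned to genes, and its lowest level was 58900 CPM. Transcripts known from white cells included the neutrophil gene S100a9 with a mean of 343 CPM, the macrophage and neutrophil gene Lyz2 with 353 CPM and the B cell gene Cd79a with 60.4 CPM. The labels do not say whether libraries of different weeks came from separate animals, so the p-values below measure the spread between samples. By sex as read from the counts, the same set of animals was not sampled at every week.

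MIR29B against the scrambled control addressed whether the microRNA lowered its targets. Dnmt3a, a de novo DNA methyltransferase at chromosome 12, 3806007 to 3914443, stood at 2.82 ± 1.64 CPM (SD, n = 3) with MIR29B and 2.55 ± 1.95 CPM with the control at week 2 and 2 mg/kg. At 3 mg/kg it stood at 1.47 ± 1.3 CPM with MIR29B and 2.74 ± 2.49 CPM with the control. At week 4 it was 4.66 ± 0.285 CPM against 2.07 ± 0.297 CPM at 2 mg/kg, the higher level being in the MIR29B group, and 2.26 ± 1.23 CPM against 2.33 ± 1.73 CPM at 3 mg/kg. None of these differences passed the test: the log2 fold changes were 0.14 ± 0.73 (SE) and -0.81 ± 0.76 at week 2, with edgeR adjusted p of 0.982 and 0.877. They were 1.17 ± 0.74 and -0.06 ± 0.74 at week 4, both with an adjusted p of 1. At week 0 the differences were -0.76 ± 0.75 and -0.13 ± 0.74. Single libraries held as few as 2 counts of Dnmt3a, so small differences were not detectable at this depth.

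The other genes that write or erase DNA methylation did not differ between the arms by the test either. Dnmt1, the maintenance methyltransferase, had log2 fold changes of 1.24 ± 0.49 at week 2 and 2 mg/kg and 1.35 ± 0.49 at 3 mg/kg, with adjusted p of 0.482 and 0.633. Dnmt3b lay between -0.74 ± 1.32 and 0.9 ± 1.43 over the 6 comparisons, Tet2 between -1.24 ± 0.84 and 0.53 ± 0.87, and Tet3 between -0.8 ± 0.38 and 0.7 ± 0.38. Tet1 had no counts with MIR29B at week 2 and 2 mg/kg, where the control held 10 counts in 3 libraries, and none with the control at week 4 and 2 mg/kg, where MIR29B held 12 counts. The adjusted p of these differences were 0.603 and 1. Of 15 tested genes of the DNA methylation machinery, 0 were called in any comparison of the arms, and 0 when adjusted over the list alone. The list's median log2 fold changes at week 2 were 0.05 and 0.02, and at week 4 they were 0.19 and -0.06.

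Regulators of fetal globin were at levels that the test did not separate between the arms. Bcl11a, a repressor of fetal globin genes at chromosome 11, 24078056 to 24174123, stood at 3.47 ± 1.24 CPM with MIR29B and 0.947 ± 0.637 CPM with the control at week 4 and 3 mg/kg. That log2 fold change of 1.83 ± 0.61 had an unadjusted p of 0.0051 and an adjusted p of 1. Its value at week 4 and 2 mg/kg was 0.3 ± 0.6. Myb lay between -0.39 ± 1.07 and 0.69 ± 1.08, Klf1 between -1.23 ± 0.61 and 0.51 ± 0.6, Gata1 between -0.28 ± 0.42 and 0.68 ± 0.42, and Zbtb7a between -0.61 ± 0.5 and 0.54 ± 0.49. Of 44 tested fetal globin regulators, 0 were called, and adjusted over the list alone 1 was, Zfpm1 at week 2 and 2 mg/kg (2.74 ± 0.59, adjusted p of 0.203 over all genes).

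Transcripts of known miR-29 targets as a group were not lower with MIR29B by the test. Of 41 tested targets from the literature, 0 were called in each of the 6 comparisons, and 0 when adjusted over the list alone. Their median log2 fold changes were -0.23 and -0.15 at week 2 and 0.36 and -0.06 at week 4, and camera's adjusted p at the preset correlation ran from 0.116 at week 0 to 0.908. Mcl1, a survival factor and miR-29 target, lay between -0.7 ± 0.36 at week 0 and 0.36 ± 0.36 at week 4. The 317 tested genes with a miR-29 8-mer site in the 3' UTR had medians of -0.07 and -0.1 at week 2 and 0.17 and -0.02 at week 4. Their camera adjusted p lay between 0.0598, at week 0 and 2 mg/kg, and 0.961, and adjusted over the list alone 1 of them was called, at week 2 and 3 mg/kg. The genes with the smallest p-values were others. At week 2 and 2 mg/kg these were Epn1 (1.73 ± 0.35), Psmf1 (1.6 ± 0.33) and Zfpm1, with adjusted p of 0.193, 0.193 and 0.203. At week 2 and 3 mg/kg they were Oas1e (2.66 ± 0.6), Kmt5a (1.67 ± 0.38) and Rnase4, which had no counts with MIR29B and 108 with the control, at least 30.1-fold lower (15-fold if each fragment was counted as 2), all with an adjusted p of 0.454. At week 4 the smallest included Nfkbie (2.11 ± 0.53), Nudt1 (-4.82 ± 1.22) and Ccdc93 (2.12 ± 0.56) at 2 mg/kg, and Hyou1 (1.44 ± 0.36), Slc2a9 (3.24 ± 0.83) and Eif5a2 (1.58 ± 0.43) at 3 mg/kg, all with an adjusted p of 1. At week 0 they were Ebi3 (-2.94 ± 0.64), Cpne2 (-3.38 ± 0.81) and Adgrg3 (-3.25 ± 0.81) at 2 mg/kg and Osm (-2.02 ± 0.45), Nfil3 (-2.03 ± 0.51) and Pi16 (-1.84 ± 0.5) at 3 mg/kg, with adjusted p of 0.726 to 1.

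**Figure D1:**
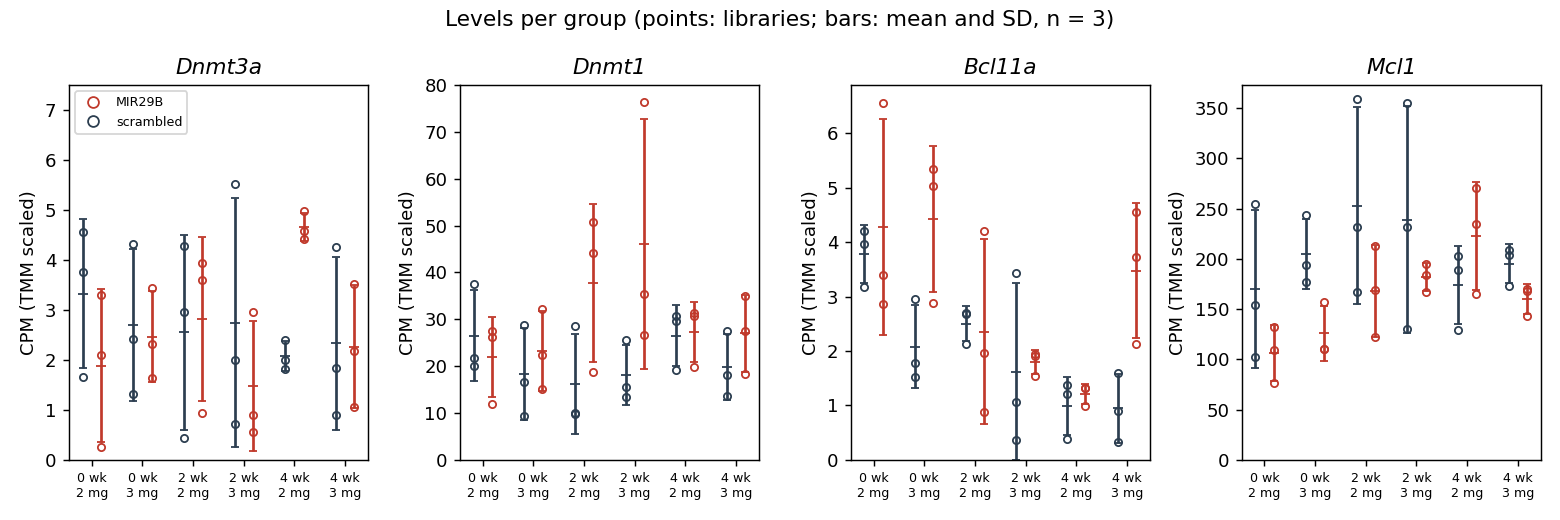
Levels of Dnmt3a, Dnmt1, Bcl11a and Mcl1 in TMM-scaled CPM (vertical axis) by week and dose (horizontal axis), with open circles for single libraries and bars for the mean and SD of 3 libraries per group, MIR29B in red and scrambled control in dark blue. The libraries of the arms overlap in most groups; Dnmt3a at week 4 and 2 mg/kg is higher with MIR29B (4.66 against 2.07 CPM), a difference that did not pass the test.

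Across all 11953 genes, edgeR called 0 genes at week 0 at either dose, 0 at week 2 and 0 at week 4. At an unadjusted p under 0.05 there were 553 and 407 genes at week 0, 983 and 847 at week 2, and 269 and 382 at week 4, for 2 and 3 mg/kg, where chance gives 598. DESeq2 called 46 genes at week 2 and 2 mg/kg, 36 higher and 10 lower, and 5 at week 2 and 3 mg/kg, and 0 in the other 4 comparisons. Voom with sample weights called 1 gene at week 0 and 3 mg/kg and 1 at week 2 and 2 mg/kg, but its weights depend on the order of the genes. With genes sorted by falling count it called 616 and 170 at week 0 and 0 at weeks 2 and 4, and with weights by REML, which do not depend on the order, 14 at week 0 and 3 mg/kg and 5 at week 2 and 2 mg/kg. With the transcript length index as a term edgeR called 24 at week 2 and 2 mg/kg. With no filter on low counts edgeR called 26 and 33 genes at week 0, 31 and 36 at week 2, and 5 and 4 at week 4. In simulated data 1 of 200 genes with a 2-fold change was recovered by this comparison of 3 with 3 libraries, so a count of 0 leaves changes of that size open. At week 2 and 2 mg/kg, edgeR called 2 genes without scrambled replicate 1, 2 without scrambled replicate 2, 1 without scrambled replicate 3 and 2 without MIR29B replicate 1. At week 2 and 3 mg/kg it called 1 without scrambled replicate 3.

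Cell type markers separated the arms at week 0 by camera at its preset correlation. Whether dosing had begun by then was not established, so an effect of MIR29B cannot be told apart from a difference between the animals. At week 0 and 3 mg/kg, all 25 tested neutrophil markers were lower with MIR29B (median log2 fold change -1.47), as were 27 of 31 inflammatory response genes (median -1.19), while all 20 B cell markers were higher (median 0.86). No member was called over all genes; adjusted over the list alone, 8 neutrophil markers and 8 inflammatory genes were called. Camera's adjusted p were 8.73e-18, 5.06e-15 and 7e-08, against adjusted p = 0.424, 0.424 and 0.728 with an estimated correlation. At week 0 and 2 mg/kg, neutrophil markers (-0.58) and inflammatory genes (-0.85) also lay lower, with camera adjusted p of 0.0052 and 0.00489, and adjusted p = 0.838 and 0.765 with an estimated correlation. Ribosomal protein genes lay higher at week 0, with medians of 0.83 and 0.43 and camera adjusted p of 2.07e-23 and 2.6e-07. Their adjusted p with an estimated correlation were 0.728 and 0.838. The transcript length index, which is lower where short transcripts take more of the counts, had a week 0 mean of -1.05 with MIR29B and -0.59 with the control. In week 0 2 mg/kg MIR29B replicates 2 and 3 it was -2.31 and -1.41, and ribosomal protein genes took 12.28% and 10.24% of the counts.

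At weeks 2 and 4 the lists called by camera were again mostly markers of cell types. Neutrophil markers lay lower with MIR29B at week 2, with medians of -1 and -0.8, and at week 4 and 3 mg/kg, with a median of -0.77. Their adjusted p with an estimated correlation were 0.765, 0.765 and 0.728. Erythroid genes lay higher at week 2, with medians of 0.39 and 0.55, and lower at week 4 and 2 mg/kg, with a median of -0.25, and adjusted p = 0.728, 0.728 and 0.765 with an estimated correlation. Inflammatory response genes went opposite ways at week 4, with medians of 0.55 at 2 mg/kg and -0.54 at 3 mg/kg, and adjusted p = 0.728 and 0.765 with an estimated correlation. Platelet and megakaryocyte markers were called higher at week 2 and 3 mg/kg with a mean of 0.03 but a median of -0.07, and lower at week 4 and 3 mg/kg with a median of -0.55. Their adjusted p with an estimated correlation were 0.765 and 0.728. The 9 tested mouse globin genes were called higher at week 2 and 3 mg/kg (median 0.81) and lower at week 4 and 3 mg/kg (median -0.49), with an adjusted p of 0.728 for both at an estimated correlation. These mice carry human globin genes in place of the mouse ones, so counts on replaced mouse genes, such as Hba-a1 with 7.96 to 115 CPM, do not show expression of those genes, and the source of these reads was not tested. In all, camera called 48 of 114 list tests at the preset correlation, 0 with an estimated correlation, and fry called 0; the remaining lists called had an adjusted p between 0.424 and 0.87 with an estimated correlation. Other divisions of the same libraries, with arm labels exchanged, gave a median of 44 called lists.

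The difference between doses in the MIR29B effect did not reach the threshold for any gene. At week 2 the smallest p-values belonged to Zfp825 (2.44 ± 0.56), Acaa2, a mitochondrial thiolase (-2.52 ± 0.6), and Erfe, the red cell hormone erythroferrone (-6.51 ± 1.59), with adjusted p of 0.637. At week 4 they belonged to Nfkbie (-2.75 ± 0.73), Cdc42ep4 (-2.87 ± 0.76) and Cd200 (4.51 ± 1.25), with adjusted p of 1. The edgeR test called 0 genes at each week, with 688 and 410 genes at an unadjusted p under 0.05, and DESeq2 called 0. With no filter on low counts edgeR called 20 and 5, and at week 2 it called 3 without week 2 2 mg/kg scrambled replicate 1 and 3 without replicate 3.

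From week 0 to week 2, blood of the MIR29B arm gained transcripts of innate immune activation. Nfkbia, the inhibitor of NF-kappa-B that is itself induced by it, at chromosome 12, 55489410 to 55492647, rose from 21.5 ± 5.35 to 132 ± 22.3 CPM (SD, n = 6), a log2 fold change of 2.62 ± 0.36 (SE). Trem1, a receptor that amplifies inflammation in neutrophils and monocytes, at chromosome 17, 48232768 to 48246924, rose from 3.97 ± 1.9 to 34.6 ± 14.1 CPM (3.11 ± 0.4). Maff, a small Maf transcription factor at chromosome 15, 79346621 to 79359076, rose from 0.172 ± 0.167 to 6.35 ± 2.15 CPM (5.24 ± 0.54). The adjusted p were 4.08e-05, 1.26e-05 and 3.64e-07, and each was higher in 6 of 6 samples than the week 0 mean. The other large rises were Acod1, which makes itaconate (5.97 ± 0.96), Chst13 (4.76 ± 1.09), Snai1 (4.71 ± 0.74), the neutrophil chemokine Cxcl1 and the coagulation initiator F3. Cxcl1 and F3 had no counts at week 0 in this arm and were at least 22.2-fold and 13.4-fold higher by a floor of 3 counts over the group, or 11.1-fold and 6.72-fold if each fragment was counted as 2. DESeq2 gave neither an adjusted p, and F3 was not called without the libraries with over 5% ribosomal RNA. Summed over the week 0 libraries, Snai1 and Chst13 held 6 and 10 counts, so their folds rest on few counts.

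Of 31 inflammatory response genes, 15 rose and 1 fell at week 2 of the MIR29B arm, and 17 were called when adjusted over the list alone. Among those that rose were Tnf (3.55 ± 0.6), a cytokine, and Ccrl2 (2.21 ± 0.34), a chemoattractant receptor. The gene that fell was Fos, an immediate early transcription factor. Of 25 neutrophil markers, 12 rose and 0 fell, and 19 were called over the list alone, among them the decoy receptor Il1r2 (3.62 ± 0.54) and G0s2 (2.79 ± 0.44). Camera gave adjusted p of 1.6e-11 and 1.65e-15, against adjusted p = 0.44 for both with an estimated correlation, and fry gave 0.00549 for both. Of 23 monocyte and macrophage markers, 2 rose, Cd14 (2.76 ± 0.41) and Nr4a1 (1.18 ± 0.33), and the list was not called (camera adjusted p of 0.139). Of 12 eosinophil and basophil markers, Hdc, which makes histamine, rose (1.95 ± 0.39), with a camera adjusted p of 0.111 for the list. Nr4a1 lost its call in 6 of 12 fits that each left out 1 library.

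A few lymphocyte and interferon genes fell at week 2 of the MIR29B arm. Of 19 NK cell markers, 1 fell, Klra8 (-2.96 ± 0.7), with a median of -1.12 and 7 called over the list alone. Of 20 B cell markers, 2 fell, Cr2 (-1.74 ± 0.45) and Tnfrsf13c (-1.36 ± 0.39), and 2 were called over the list alone. Of 39 interferon-stimulated genes, 2 fell, Ifit2 (-1.92 ± 0.48) and Ifit1bl1 (-1.78 ± 0.49). Camera's adjusted p for these lists were 1.75e-05, 0.0317 and 0.000169, and adjusted p = 0.61, 0.761 and 0.677 with an estimated correlation; fry gave 0.0479 for the NK cell markers. T cell markers had a median of -0.25 and no called member (camera adjusted p of 0.0588). The largest falls were Eri2 (-5.05 ± 1.34), Zfp712 (-4.91 ± 1.21), Zfp790 (-4.38 ± 1.15), AW146154 (-4.18 ± 1.12), the chromatin remodeler Hells (-4.15 ± 1.21) and Zfp677 (-3.56 ± 1.03). Each of these 6 lost its call without at least 1 single library, Zfp712 without week 2 2 mg/kg MIR29B replicate 1 alone. Klra8 lost it without week 0 3 mg/kg MIR29B replicate 2. Of 12 fits that each left out 1 library, Cr2 lost its call in 3, Eri2 and AW146154 in 5, Ifit1bl1 in 7, Zfp677 in 8, Tnfrsf13c in 9 and Hells in 10, and Zfp790 lost it without replicate 3 of either dose at week 0. Ifit2 lost its call without the libraries with over 5% ribosomal RNA. Summed over the week 2 libraries, Eri2 held 2 counts and Zfp712, AW146154 and Hells 4 each, so their folds rest on few counts.

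Some red cell genes rose at week 2 of the MIR29B arm. Of 49 erythroid genes, 5 rose, and 9 were called over the list alone. The glucose transporter Slc2a1 (1.57 ± 0.28) and the membrane protein gene Ank1 (1.39 ± 0.32) were among them. The list had a camera adjusted p of 0.00215, and adjusted p = 0.721 with an estimated correlation. Of 44 fetal globin regulators, 4 rose and 1 fell, with Zfpm1, the GATA1 cofactor (1.98 ± 0.41), Mafk (1.18 ± 0.28) and Klf3 (0.84 ± 0.21) among those that rose. That list was not called (0.161), nor were the 9 mouse globin genes, of which 0 changed. Of 31 oxidative stress and NRF2 genes, Gsr (1.19 ± 0.31) and Pgd (1.12 ± 0.35) rose, and of 25 heat shock and unfolded protein genes Herpud1 rose (0.99 ± 0.21). Camera gave these lists adjusted p of 0.00212 and 0.0463, and adjusted p = 0.677 and 0.761 with an estimated correlation. Of 24 platelet and megakaryocyte markers Rgs18 fell (-1.33 ± 0.38). Klf3 lost its call without 2 of 12 libraries in turn, Gsr without 3, Rgs18 without 8 and Pgd without 11. Ank1 and Mafk lost theirs without the libraries with over 5% ribosomal RNA.

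Targets of miR-29 did not fall as a group from week 0 to week 2 of the MIR29B arm. Of 41 literature targets 2 rose, the apoptosis gene Bbc3 (1.46 ± 0.29) and Grn (1.17 ± 0.34), and 0 fell, with a median of 0.04. Of 317 genes with an 8-mer site, 9 rose and 8 fell, such as Metrnl (1.46 ± 0.31), Sike1 (-1.46 ± 0.32) and Zfp26 (-1.93 ± 0.43). Neither list was called (camera adjusted p of 0.851 and 0.438). Grn lost its call in 8 of 12 fits that each left out 1 library, and Bbc3 and Zfp26 lost theirs without the libraries with over 5% ribosomal RNA. None of 15 DNA methylation genes was called.

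In all, 412 genes rose and 238 fell from week 0 to week 2 in the MIR29B arm, 650 of 11953. The count was 346 without week 0 2 mg/kg MIR29B replicate 3, 293 without week 0 3 mg/kg replicate 3, 377 without week 2 2 mg/kg replicate 1, and 361 without week 2 3 mg/kg replicate 3. DESeq2 called 1128 genes, and without the libraries with over 5% ribosomal RNA, which include 2 of the 3 at week 2 and 2 mg/kg, 164 were called.

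By week 4 of the MIR29B arm the inflammatory and neutrophil genes were again above week 0. Maff stood at 12.8 ± 7.18 CPM (SD, n = 6), a log2 fold change of 6.2 ± 0.55 (SE) and an adjusted p of 6.99e-09. Trem1 stood at 56.9 ± 25.9 CPM (3.77 ± 0.41, adjusted p of 4.66e-07), and Il1r2, at chromosome 1, 40074079 to 40125231, at 31.3 ± 19.2 CPM (4.36 ± 0.55, adjusted p of 4.18e-06). Each was higher in 6 of 6 samples than the week 0 mean. Acod1 (7.17 ± 0.99), Snai1 (5.65 ± 0.73) and the chemokine Cxcl3 (5.64 ± 1.08) rose as well, and F3 and Cxcl1 were at least 20.3-fold and 24.7-fold higher by the floor of 3 counts over the group, or 10.2-fold and 12.4-fold if each fragment was counted as 2.

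Of 31 inflammatory response genes, 17 rose at week 4 of the MIR29B arm and 1, Fos, fell, with 22 called over the list alone. Tlr2, a receptor of bacterial lipoproteins (3.06 ± 0.45), Nfkbiz (3.26 ± 0.48) and Ccrl2 (2.53 ± 0.34) were among them. Of 25 neutrophil markers, 8 rose and 0 fell, including G0s2 (3.78 ± 0.45), and of 23 monocyte and macrophage markers Cd14 (3.33 ± 0.42) and Nr4a1 (1.71 ± 0.33) rose. Hdc rose among 12 eosinophil and basophil markers (2.15 ± 0.39). The camera adjusted p of these 4 lists were 9.87e-18, 2.48e-12, 4.04e-05 and 0.00342, and adjusted p = 0.261, 0.501, 0.677 and 0.61 with an estimated correlation. Fry called the inflammatory (0.00043), neutrophil (0.0132) and eosinophil and basophil (0.0363) lists. A score of 14 neutrophil granule and surface markers moved with these genes, from 3.51 ± 0.52 at week 0 to 4.92 ± 0.38 at week 2 and 4.46 ± 0.41 at week 4 (mean log2 CPM, SD, n = 6).

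A few B cell genes fell by week 4 of the MIR29B arm. Cxcr5, the chemokine receptor that guides B cells into follicles, at chromosome 9, 44511787 to 44561877, fell from 7.99 ± 3.85 to 2.11 ± 1.05 CPM (SD, n = 6), a log2 fold change of -1.96 ± 0.38 (SE) with an adjusted p of 0.00157, below the week 0 mean in 6 of 6 samples. Of 20 B cell markers, Cd79b (-1.74 ± 0.47) and Vpreb3 (-2.28 ± 0.62) fell, and 3 were called over the list alone; both lost the call without several single libraries, the number being 9 of 12 for Cd79b and 10 for Vpreb3. The T cell markers had a median of -0.32 and no called member. The camera adjusted p were 0.000444 and 0.00517, and adjusted p = 0.677 and 0.696 with an estimated correlation. Other large falls were Saysd1 (-3.09 ± 0.65), Cd200 (-2.7 ± 0.59) and Mcc, which had 32 counts at week 0 and none at week 4, at least 13-fold lower by the floor (6.48-fold if each fragment was counted as 2). Mcc lost its call without 10 of 12 libraries in turn. Of 35 cell cycle genes Birc5 fell (-1.63 ± 0.44), and of 84 genes listed as ribosomal protein genes Rpl7l1 fell (-1.01 ± 0.26). Rpl7l1 was listed by its symbol alone, which does not show that it encodes a ribosomal protein. The calls of Birc5 and Rpl7l1 were lost without 7 and 3 of the 12 libraries in turn. Those lists were called lower with camera adjusted p of 0.0175 and 1.22e-05, and adjusted p = 0.677 and 0.761 with an estimated correlation. Interferon-stimulated genes had a median of -0.23, a camera adjusted p of 0.0465 and an adjusted p of 0.761 with an estimated correlation.

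Genes expected to answer to MIR29B or to oxidative stress included a few that rose by week 4. Of 41 literature targets of miR-29, the growth factor gene Vegfa (2.26 ± 0.53) and Bbc3 (1.1 ± 0.29) rose and 0 fell. That list was called higher, with a median of 0.22, a camera adjusted p of 0.00579 and an adjusted p of 0.677 with an estimated correlation. Of 317 genes with an 8-mer site 11 rose and 0 fell, where 316 of all 11953 tested genes rose and 53 fell. The costimulatory gene Cd80 (5.45 ± 0.82), the phosphatase gene Ptp4a1 (1.51 ± 0.25) and Metrnl (1.74 ± 0.31) were named by p-value. Of 31 oxidative stress and NRF2 genes, the cystine transporter Slc7a11 (2.85 ± 0.57) and Gsr (1.22 ± 0.31) rose. Of 25 heat shock and unfolded protein genes 4 rose, among them Hspa5 (0.86 ± 0.23), Herpud1 (0.94 ± 0.21) and Hspa1a (1.8 ± 0.5). Of 49 erythroid genes Slc2a1 (2.12 ± 0.28) and Aqp1 (1.02 ± 0.3) rose, and of 44 fetal globin regulators Zfpm1 (1.78 ± 0.4) and Mafk (1.05 ± 0.28). Vegfa lost its call without week 4 2 mg/kg MIR29B replicate 1 and Zfpm1 without replicate 2 of that group. Gsr lost it without 4 of 12 libraries in turn, Mafk without 6, Hspa1a without 8, Bbc3 and Hspa5 without 9 and Aqp1 without 10, and Herpud1 lost it with no filter on low counts. Of 15 DNA methylation genes 0 were called.

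In all, 316 genes rose and 53 fell by week 4 in the MIR29B arm, 369 of 11953. The count was 206 without week 0 2 mg/kg MIR29B replicate 2, 224 without its replicate 3, 233 and 196 without week 0 3 mg/kg replicates 2 and 3, 211 without week 4 2 mg/kg replicate 1 and 239 without week 4 3 mg/kg replicate 1. DESeq2 called 782 genes, and with the compared libraries alone in the fit edgeR called 626.

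**Figure D2:**
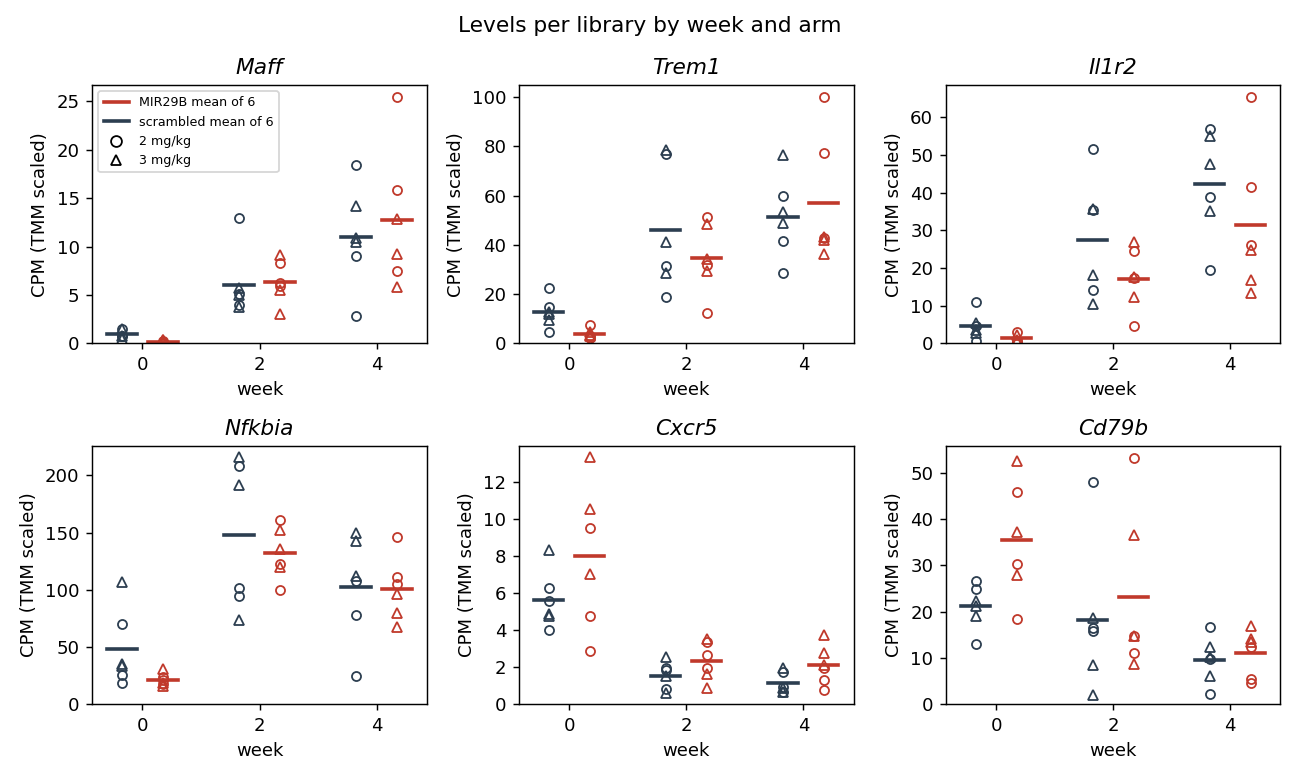
Levels of Maff, Trem1, Il1r2, Nfkbia, Cxcr5 and Cd79b in TMM-scaled CPM (vertical axis) by week (horizontal axis), with circles for libraries at 2 mg/kg, triangles for 3 mg/kg and lines for the mean of 6 libraries, MIR29B in red and scrambled control in dark blue. The inflammatory genes are higher at weeks 2 and 4 in both arms, as Trem1 from 3.97 to 34.6 CPM with MIR29B and from 12.6 to 45.9 CPM with the control, and Cxcr5 is lower.

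The scrambled arm showed rises of the same kind from week 0 to week 2. Trem1 rose from 12.6 ± 5.98 to 45.9 ± 25.6 CPM (SD, n = 6), a log2 fold change of 1.86 ± 0.38 (SE) with an adjusted p of 0.00892. Il1r2 rose from 4.63 ± 3.49 to 27.6 ± 15.9 CPM (2.55 ± 0.5, adjusted p of 0.00642), and Tnf from 0.518 ± 0.398 to 5.48 ± 3.41 CPM (3.25 ± 0.58, adjusted p of 0.00309). Each was higher in 6 of 6 samples than the week 0 mean. Fos fell (-1.89 ± 0.3, adjusted p of 0.00171) in 6 of 6 samples. The largest rises were Cstdc5 (5.81 ± 1.57), the ephrin receptor Epha2 (5.02 ± 1.05), Rab3c (4.88 ± 1.34), Cxcl1 (4.51 ± 1.25), the anti-inflammatory cytokine Il10 (4.26 ± 1.15) and Lgr4, which had no counts at week 0 and was at least 12.4-fold higher (6.22-fold if each fragment was counted as 2). Of these 6, Epha2 kept its call in each of 12 fits that left out 1 library, though DESeq2 gave it no adjusted p, and the others lost it in 7 or 9. Summed over the week 0 libraries, Cstdc5, Epha2, Rab3c and Cxcl1 held 8, 4, 4 and 2 counts, so their folds rest on few counts.

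Of 31 inflammatory response genes, 6 rose and 1 fell at week 2 of the scrambled arm, with 15 called over the list alone. Nfkbia was among those that rose (1.64 ± 0.35). Of 25 neutrophil markers 10 rose and 0 fell, with 16 called over the list alone, among them Wfdc21 (2.77 ± 0.52). Of 23 monocyte and macrophage markers Cd14 rose (1.91 ± 0.4). The camera adjusted p of these lists were 1.22e-05, 1.36e-13 and 0.00429, and adjusted p = 0.618, 0.47 and 0.696 with an estimated correlation; fry called the neutrophil list (0.0291). Of 39 interferon-stimulated genes 4 fell, among them Rsad2 (-1.29 ± 0.3), Ifit1bl1 (-2.06 ± 0.5) and Herc6 (-1.24 ± 0.3), and 9 were called over the list alone. NK cell markers had a median of -1.06 with 0 called members and 6 over the list alone. For both lists camera gave adjusted p of 1.22e-05 and 4.69e-05, adjusted p = 0.618 and 0.61 with an estimated correlation, and fry gave 0.0363 for both. Of 20 B cell markers Cr2 fell (-1.76 ± 0.46), of 24 platelet and megakaryocyte markers Rgs18 (-1.55 ± 0.38), and no T cell marker was called. These 3 lists were called lower, with camera adjusted p of 0.043, 0.00372 and 0.00111, and adjusted p = 0.764, 0.677 and 0.677 with an estimated correlation. Without week 0 3 mg/kg scrambled replicate 2 Cd14 and Nfkbia lost their calls, and Nfkbia also without week 2 2 mg/kg scrambled replicate 3. The interferon-stimulated genes named, Cr2 and Rgs18 lost theirs in 4 to 7 of 12 fits that each left out 1 library. The neutrophil score stood at 4.42 ± 0.84 at week 0, 5.47 ± 0.89 at week 2 and 4.91 ± 0.82 at week 4 (SD, n = 6).

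Single genes of other groups passed in the scrambled arm at week 2 as well. Of 84 ribosomal protein genes 3 rose, Rps9 (1.31 ± 0.36), Rplp2 (1.58 ± 0.44) and Rpl8 (1.19 ± 0.34), with 35 called over the list alone, a median of 0.75 and a camera adjusted p of 3.3e-13. With each library's transcript length index as a term these 3 were not called, with log2 fold changes of 0.45 ± 0.19, 0.46 ± 0.24 and 0.33 ± 0.21. That index, which is lower where short transcripts take more of the counts, had a mean of -0.59 at week 0 and -1.33 at week 2 of this arm. Its lowest value, -2.894, was in week 2 3 mg/kg scrambled replicate 1, where ribosomal protein genes took 15.71% of the counts. Of 31 oxidative stress and NRF2 genes Pgd (1.65 ± 0.35) and Hmox1, which degrades heme (1.31 ± 0.38), rose, with 11 called over the list alone and a camera adjusted p of 3.23e-05. Both lists had an adjusted p of 0.677 with an estimated correlation. Of 49 erythroid genes Slc2a1 (1.42 ± 0.28), Alad (2.63 ± 0.67) and Slc25a38 (0.99 ± 0.26) rose and 2 fell. Herpud1 rose (0.73 ± 0.21). Of 44 fetal globin regulators Spop (-0.87 ± 0.21) and Lmo2 (-0.87 ± 0.24) fell, and of 41 miR-29 targets Itga6 fell (-1.16 ± 0.33). Of 317 genes with an 8-mer site 1 rose and 3 fell, Zfp322a (-1.88 ± 0.51), Ppil4 (-1.05 ± 0.29) and Dlg2 (-2.69 ± 0.74). The largest falls were Zfp781, which had 32 counts at week 0 and none at week 2, at least 10.9-fold lower (5.43-fold if each fragment was counted as 2), Pcdh7 (-4.73 ± 1.36), Polq (-4.64 ± 1.23), Mcm8 (-4.39 ± 1.18), Brip1 (-4.24 ± 1.22) and the interferon-induced Iigp1 (-4.21 ± 1). Apart from Slc2a1, each gene named among these groups lost its call in 3 to 11 of 12 fits that each left out 1 library. Summed over the week 2 libraries, Polq, Mcm8 and Brip1 held 2 counts each, so their folds rest on few counts.

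In all, 252 genes rose and 132 fell from week 0 to week 2 in the scrambled arm, 384 in number, and this count depended on single libraries. Without week 0 2 mg/kg scrambled replicates 1 and 3 it was 170 and 82, without week 0 3 mg/kg replicates 1 and 2 it was 68 and 42, without week 2 2 mg/kg replicates 1, 2 and 3 it was 950, 588 and 44, and without week 2 3 mg/kg replicates 1 and 3 it was 161 and 677. With the compared libraries alone in the fit it was 0, so no gene named for this comparison was called there, while DESeq2 called 1019 and voom with sample weights 160.

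Fewer genes passed at week 4 of the scrambled arm, with inflammatory and neutrophil genes again among the highest. Maff rose from 0.967 ± 0.419 to 11 ± 5.2 CPM (SD, n = 6), a log2 fold change of 3.49 ± 0.45 (SE) with an adjusted p of 5.99e-05. Il1r2 rose to 42.1 ± 14.1 CPM (3.19 ± 0.51, adjusted p of 0.000833) and Trem1 to 51.4 ± 16.3 CPM (2.01 ± 0.38, adjusted p of 0.00553), each above the week 0 mean in 6 of 6 samples. Cxcr5 fell from 5.63 ± 1.54 to 1.14 ± 0.565 CPM (-2.27 ± 0.39, adjusted p of 0.00191) in 6 of 6 samples. The other large changes were rises of Epha2 (4.69 ± 1.05), Cxcl3 (4.42 ± 0.93), Acod1 (3.68 ± 0.8), Snai1 (3.66 ± 0.62) and Rhov (3.39 ± 0.76). Falls were seen in Tifab (-2.16 ± 0.49), Tagap (-1.65 ± 0.33), Fam78a (-1.6 ± 0.34), Nxpe3 (-1.56 ± 0.29) and the ferric reductase gene Cybrd1, which had 40 counts at week 0 and none at week 4, at least 11.9-fold lower (5.95-fold if each fragment was counted as 2). Epha2, Rhov, Cxcl3, Acod1, Tifab, Fam78a and Cybrd1 lost their calls in 4 to 9 of 12 fits that each left out 1 library, while Maff, Il1r2, Trem1, Cxcr5, Snai1, Tagap and Nxpe3 kept theirs in all 12.

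Of 31 inflammatory response genes 1 rose, Cxcl3, and 1 fell, Fos (-1.55 ± 0.3), at week 4 of the scrambled arm, and 13 were called over the list alone. Of 25 neutrophil markers 3 rose, with G0s2 (1.85 ± 0.41) beside Il1r2 and Trem1, and of 23 monocyte and macrophage markers Cd14 rose (2.15 ± 0.4). Of 49 erythroid genes Slc2a1 rose (1.76 ± 0.28), and of 317 genes with an 8-mer site Ptp4a1 rose (1.13 ± 0.24). G0s2 lost its call without 7 of 12 libraries in turn and Ptp4a1 without 5. The camera adjusted p of the first 4 lists were 1.11e-06, 1.74e-08, 0.000215 and 0.00147, and adjusted p = 0.61, 0.61, 0.677 and 0.706 with an estimated correlation. Ribosomal protein genes (median 0.59), oxidative stress genes (0.28) and heat shock genes (0.4) were called higher without a called member, with camera adjusted p of 9.87e-18, 0.00175 and 0.00128. B cell (-0.49), T cell (-0.39), platelet (-0.7) and interferon-stimulated (-0.26) lists were called lower without a called member, with 0.000115, 0.00212, 0.000196 and 0.0296. The adjusted p with an estimated correlation were 0.677 for the first 6 of these lists and 0.721 for the last.

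In all, 43 genes rose and 12 fell by week 4 in the scrambled arm, 55 in number. The count was 29 without week 0 2 mg/kg scrambled replicate 3, 35 and 28 without week 0 3 mg/kg replicates 1 and 2, and 33 without week 4 2 mg/kg replicate 2, while DESeq2 called 144, voom with sample weights 393 and edgeR with no filter on low counts 139.

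**Figure D3:**
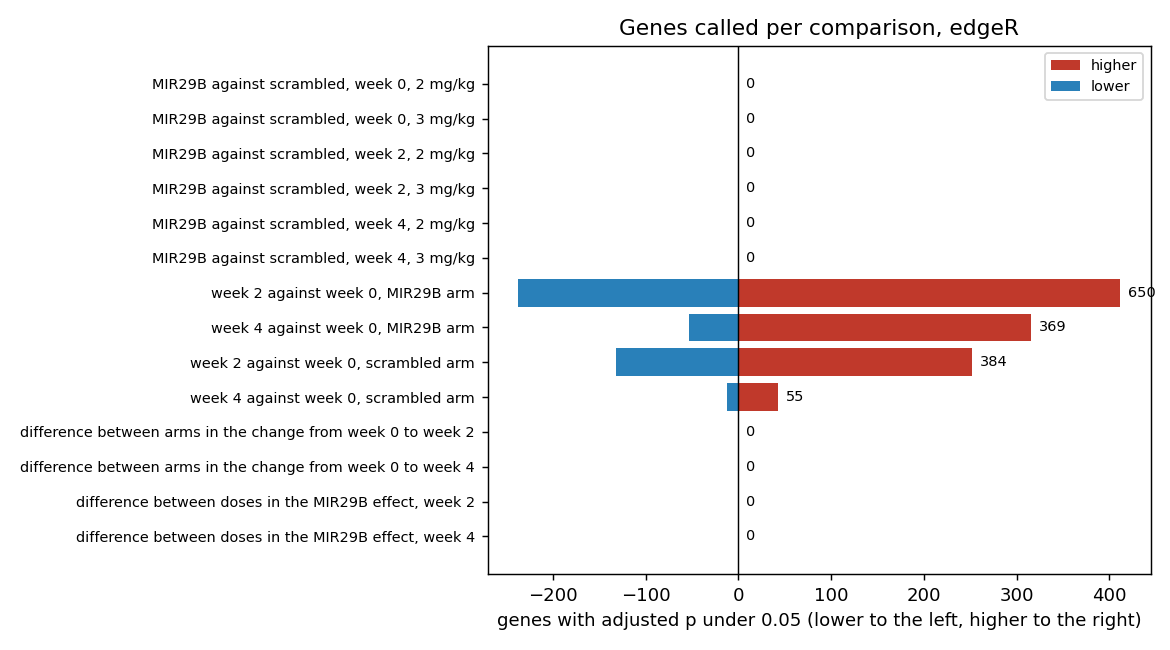
Number of genes called by edgeR at an adjusted p under 0.05 (horizontal axis) in each comparison (vertical axis), with genes higher to the right in red and genes lower to the left in blue, out of 11953 genes tested. Genes were called between weeks within an arm (650, 369, 384 and 55) and 0 were called between the arms, between arms in the change over time, or between doses.

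The genes that changed over time in the scrambled arm overlapped those of the MIR29B arm. At week 2 the arms shared 101 genes that rose, where independent lists would share 8.69, and 60 that fell, where 2.63 would be shared. At week 4 they shared 39 that rose and 5 that fell, where 1.14 and 0.0532 would be shared. Of the 412 genes that rose at week 2 with MIR29B, 93.4% had a positive fold change in the scrambled arm, and of the 316 that rose at week 4, 99.4% did. Genes are not independent replicates, so these counts carry no p-value.

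The difference between arms in the change over time asked whether MIR29B added to these changes. Maff had the second smallest p-value for week 4, with a rise larger by 2.71 ± 0.69 on the log2 scale in the MIR29B arm, where its week 0 level was 0.172 ± 0.167 CPM against 0.967 ± 0.419 CPM in the scrambled arm. Its adjusted p was 0.78, as for Cybrd1 and Src (5.55 ± 1.48). For week 2 the smallest p-values belonged to Cit (2.95 ± 0.69), Mical3 (2.49 ± 0.63) and Atxn7l1 (1.62 ± 0.42), with adjusted p of 0.838. The edgeR test called 0 genes for each week, with 671 and 721 at an unadjusted p under 0.05, and DESeq2 called 0. The median log2 difference of all genes was 0.117 for week 4. With no filter on low counts edgeR called 63 and 72 genes, and voom with sample weights called 0, or 306 for week 4 when transcripts were sorted by falling count before the weights were estimated. So a gene called in the MIR29B arm and not in the scrambled arm was not shown to differ between them.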

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

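The list tests of the differences between arms and between doses, the list tests of weeks against week 0, their counts over other splits, the tests of the neutrophil score by comparison, the ranks of splits by transcript length index, and the tests of transcript length and sex were chosen after the results were seen.

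The number of gene lists that differed between arms in their change over time, or between doses, was looked at by camera at its preset correlation. At that setting MIR29B against scrambled gave 48 called lists, and exchanged arm labels gave a median of 44. No other splits were run for the counts below, so they do not show more than exchanged labels would give. With an estimated correlation none of these lists was called, as given below. For the difference between arms in the change from week 0 to week 2 there were 4 lists: erythroid genes (median log2 difference 0.27), platelet and megakaryocyte markers (0.54) and inflammatory response genes (0.65) higher in the MIR29B arm, and ribosomal protein genes (-0.67) lower. For the change to week 4 there were 9 lists. Literature targets of miR-29 (0.52), neutrophil markers (0.54), eosinophil and basophil markers (1.15) and inflammatory response genes (1.06) lay higher. At week 0 the neutrophil score was 3.51 ± 0.52 with MIR29B and 4.42 ± 0.84 with the control (SD, n = 6). The inflammatory medians of MIR29B against the control were -0.85 and -1.19 at 2 and 3 mg/kg. By construction the differences in change include this gap at week 0. No gene was called between the arms at week 0, and neither list was with an estimated correlation, so a true gap was not shown. Mouse globin (-0.42), erythroid (-0.23), oxidative stress and NRF2 (-0.59), cell cycle (-0.32) and ribosomal protein genes (-0.99) lay lower.

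For the difference between doses at week 2 there were 6 lists, with B cell (0.55), T cell (0.31), NK cell (1.46) and interferon-stimulated genes (0.48) higher at 3 mg/kg and ribosomal protein genes (-0.63) lower. Platelet and megakaryocyte markers were called higher there with a mean of 0.2 and a median of -0.09. At week 4 there were 8 lists, with erythroid (0.52), heat shock and unfolded protein (1.02) and ribosomal protein genes (0.42) higher at 3 mg/kg. Neutrophil (-0.57), T cell (-0.51), platelet (-0.66), eosinophil and basophil (-0.68) and inflammatory response genes (-1.27) lay lower. None of the 4 differences had a called gene by edgeR, with 671, 721, 688 and 410 genes at an unadjusted p under 0.05 and 0 by DESeq2. With an estimated correlation between genes 0 of these lists were called, the adjusted p being 0.782 to 0.966, and fry called 0.

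Other splits of the same samples were used to ask whether chance can be excluded for the counts of genes. The counts of splits below include the real one. For week 2 against week 0 in the MIR29B arm, 2 of 100 splits within dose gave at least the real 650 genes. That share lies under the 0.05 set beforehand, though the highest other split called 809, more than the real one. For week 4 in that arm it was 2 of 100 for 369, with 403 the highest other. In the scrambled arm it was 2 of 100 for 384 at week 2, with 564 the highest other, and 1 of 100 for 55 at week 4, with 3 the highest other. For the 4 differences between arms and between doses the real count was 0. Every split reaches that whatever the data (100 of 100), so the splits cannot decide on chance there. The highest others were 635 and 0 for the arms and 2575 and 1 for the doses.

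For MIR29B against scrambled the 6 libraries of each comparison make 10 splits, too few for a share under 0.05. All 10 gave at least the real 0 in each comparison, as any split must, so this carries no information on chance. The highest others were 6 and 0 at week 0, 4 and 326 at week 2, and 0 and 0 at week 4. The highest splits called 326, 635 and 2575 genes where the real one called 0, while the median of the other splits was 0 in each of these comparisons. Such single splits may reflect a structure of the samples other than arm. The split with 326 genes ranked 1 of 10 by the difference in transcript length index between its sides, where the real split ranked 10. By the same measure the splits with 809 and 2575 genes ranked 1 of 100, where the real ones ranked 60 and 100, and the split with 635 genes ranked 5. So a shift between short and long transcripts between libraries may account for many calls in such splits. With that index as a term, edgeR called 1476 genes at week 2 of the MIR29B arm. For the list tests, 24 of 100 splits gave as many called lists as the real 48 between arms, so chance is not excluded, and 58 was the highest other. Over weeks 2 of 100 gave as many as the real 39, with 39 the highest other and a median of 28 over the other splits.

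The rise of inflammatory response genes after week 0 in both arms was weighed against technical and cellular explanations. For week 4 of the MIR29B arm, a shift between short and long transcripts was argued against. With each library's transcript length index as a term, 16 of the 17 genes that rose there were still called. Their median log2 fold change was 2.21 against 2.46 without it. More females in the later samples were argued against there in the same way, with 16 of 17 still called and a median of 2.44. For the other comparisons of weeks these 2 explanations were not tested on this list. The index fell from -0.59 at week 0 to -1.33 at week 2 of the scrambled arm. Females numbered 2 of 6 at both weeks 0 and 2 with MIR29B, and 3 of 6 with the control. More neutrophils in the later samples stay a candidate explanation that cannot be told apart from a response within cells: the inflammatory score rose by 1.05 on the log2 scale (permutation p = 1e-05, the smallest 1e+05 resamples can give), a score of 14 neutrophil markers by 0.98 (permutation p = 0.00034), and the difference of 0.07 had a permutation p of 0.774. By comparison the difference went both ways: -0.19 and 0.65 at weeks 2 and 4 of the MIR29B arm and -0.38 and 0.19 in the scrambled arm, with exact two-sided permutation p of 0.55, 0.05, 0.49 and 0.59, and 0.2 as the smallest after adjustment over the 4. Week coincides with the day of collection and with time on the pump, which the labels do not separate.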

How the results depend on the processing

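Alternatives chosen after the data were examined were the summed isoforms, every transcript tested, the halved counts, the terms for sex and transcript length, the removal of libraries with over 5% ribosomal RNA or an extreme TMM factor, the list tests over weeks, and the other forms of voom weights. In each group of values the comparisons of arms come first, in the order of week and dose. Causes were not tested unless given.

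With no filter on low counts, edgeR called 26, 33, 31, 36, 5 and 4 genes between the arms. It called 735 at week 4 of the MIR29B arm, 902 and 139 at weeks 2 and 4 of the scrambled arm, 63 and 72 for the differences between arms, and 20 and 5 for those between doses. DESeq2 called 46 and 5 genes between the arms at week 2, and 1128, 782, 1019 and 144 over time, with 565 higher and 563 lower at week 2 of the MIR29B arm.

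Voom with sample weights called 1 gene at week 0 and 3 mg/kg and 1 at week 2 and 2 mg/kg, and 2363, 1791, 160 and 393 over time. These weights depend on the order of the genes in limma's gene-by-gene update. With genes sorted by falling count it called 616 and 170 between the arms at week 0, 3516 and 3096 over time in the MIR29B arm, 704 at week 4 of the scrambled arm and 306 for the difference between arms at week 4. With weights by REML, which do not depend on the order, it called 14 at week 0 and 3 mg/kg, 5 at week 2 and 2 mg/kg, and 2824, 2362, 219 and 491 over time. Without sample weights it called 1 between the arms at week 2 and 3 mg/kg, and the counts over time stayed within 1.5 times.

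With the compared libraries alone in the fit, edgeR called 1 gene at week 4 and 3 mg/kg, 626 at week 4 of the MIR29B arm and 0 at week 2 of the scrambled arm. The replicate block used the replicate number as a term between arms and doses, and the number within arm and dose over weeks. It gave 109 genes at week 2 of the scrambled arm. The correlations of libraries with the same number had a median of 0.11 between arms and 0.05 between weeks. They do not show that the numbers pair samples. The number follows sex as read from the counts, with replicate 1 female in 12 of 12 groups, replicate 2 in 6 and replicate 3 in 0. Of 12 sets of libraries with one number, arm and dose, 8 were of one sex over the weeks. By sex as read, the other sets were not a single animal followed over weeks. The number of females changed between weeks in each arm and dose, so the same animals were not sampled at every week. The length term gave 24 genes between the arms at week 2 and 2 mg/kg, 1476 at week 2 of the MIR29B arm and 153 at week 4 of the scrambled arm. Without libraries with over 5% ribosomal RNA the counts were 164 at week 2 of the MIR29B arm and 144 and 36 in the scrambled arm, with fewer samples. Without libraries with an extreme TMM factor they were 4 between the arms at week 2 and 2 mg/kg, 220 at week 4 of the MIR29B arm, 1026 at week 2 of the scrambled arm and 5 for the doses at week 2.

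Leaving out each library in turn gave 293 to 681 and 196 to 535 genes in the MIR29B arm, 42 to 950 and 28 to 65 in the scrambled arm, 0 to 2 and 0 to 1 between the arms at week 2, and 0 to 3 for the doses at week 2. List tests called 45 to 55 between the arms and 36 to 41 over weeks, 0 and 0 with an estimated correlation, and 0 and 9 by fry. Size factors by DESeq2's method, summed isoforms, every transcript, halved counts and sex as a term kept the counts within 1.5 times. Of 137 named values that were called, 50 kept their call in every alternative. Depth limited genes such as Dnmt3a, with as few as 2 counts in a library.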

Other observations

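The test of site genes was chosen before its result was seen, while the reading of its bound was settled after. If MIR29B lowered transcripts with a matching site, genes with a miR-29 8-mer in the 3' UTR may lie below genes without one that match them in 3' UTR length and level. Over weeks 2 and 4, 223 site genes differed from 949 matched genes by -0.018 on the log2 scale, MIR29B minus scrambled, with a permutation p of 0.277 and a range of -0.05 to 0.013. The bound written beforehand for excluding the hypothesis was a lower limit above -0.05. To the third decimal the lower limit of the range equals that bound, so the hypothesis is left open. At week 0 the same difference was -0.002, with a permutation p of 0.87.

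Single genes varied widely between libraries. Hsp90aa1, a chaperone, ranged from 860 to 23500 CPM, and Rsad2, an interferon-induced gene, from 2690 to 22200 CPM. Ribosomal RNA took 15.05% of the counts in week 2 2 mg/kg MIR29B replicate 2 and 9.15% in replicate 3 of that group, against a median of 2.24%.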
